A study of Mus musculus with 6 samples.

How the data were processed

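RNA was measured in hippocampus of 6 ovariectomised mice, 3 on a control diet (OVX) and 3 on a royal jelly diet (OVX+RJ). Per the labels' protocols, tissue was frozen in liquid nitrogen, poly(A) RNA was selected and libraries were made with a directional kit. The submitters' processing notes list bcl2fastq 2.19, fastp 0.23.4, HISAT2 2.2.1, StringTie 2.2.1 and the mouse build GRCm39, without saying what each did. The strand setting of the counting, the annotation release and the treatment of reads with several alignments are not given in the sources used here, so genes that overlap on opposite strands, paralogs and processed pseudogenes can share counts. The order, day and hour of tissue collection are not given in the labels.

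The deposited table holds expected counts, 1 value per gene symbol and library, not scaled between libraries: 32067 features, each with at least 1 count in some library. At 51 features some values were not whole, and all were rounded to whole numbers, upwards where midway. Column names were matched to the groups through the library names in the labels.

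Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on the groups, which left 18629 features, 14954 of them protein-coding and 3587 with predicted-gene names. Libraries were scaled by TMM, with factors between 0.978 and 1.01. Groups were compared with glmQLFit and glmQLFTest at the installed defaults, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.134. Values per library are CPM with these factors. Standard errors of log2 fold changes are limma's moderated errors on log2 CPM with a prior count of 2. An exact permutation test of 3 against 3 cannot give a two-sided p under 0.1, so no such test is given for single genes.

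Gene lists were tested with camera on the log2 CPM, with a preset correlation of 0.01 and adjustment over 42 lists of pathways, hippocampal cell types and other tissues. Camera with an estimated correlation, its rank version and fry were run beside it, fry both for one direction and, taken up after the data were seen, for change in either direction. Members were also adjusted over each list alone. The score of a list in a library is its mean log2 CPM, minus the mean over the 6 libraries.

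The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule takes the 15 tested genes per direction with the lowest p whose groups do not overlap, leaving out predicted genes and pseudogenes, up to 4 members of each list described, and 14 genes of prior interest, of which Esr2 and Chat fell under the filter. Other choices came later. Members named outside the rule, because they were called over a list alone or with a library left out, or went against their list, were chosen after their values were seen: Sik1, Nr4a3, Gadd45b, Klf4, Jun, Cdkn1a, Plin4, Ciart and Per3. The pattern that selects oxidative phosphorylation genes had been cut short in writing and was repaired, and it and the ribosomal pattern were limited to protein-coding genes, both before any group test. The 13 lists described with named members were chosen after the list results were seen. Before the installed default of the edgeR fit was settled on, its bias-adjusted form had also been run, and it is kept as an alternative. Both forms called 0 genes.

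The test was checked on simulated counts with the means, library sizes and dispersion trend of these libraries, with 200 of 18629 genes changed in each of 5 simulations of OVX+RJ against OVX. It called 50.9% of genes changed 1.5-fold, 68.3% of those changed 2-fold and 94.8% of those changed 4-fold, and 29 of 92145 unchanged genes. Camera called 0 of 210 unshifted lists. Simulated genes vary independently, which real genes of one list do not. They also follow the dispersion trend alone, without a dispersion of their own, and no simulated library stands apart as OVX+RJ 1 does. The shares called may therefore not carry over to the real libraries.

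Alternatives were DESeq2, limma-voom, DESeq2 size factors, upper quartile scaling, a looser filter of at least 1 count and a stricter one of a mean of 50 counts, robust empirical Bayes, the replicate number as a block, each library left out in turn, other thresholds, and counts without other-tissue, mitochondrial and predicted genes. The last only dropped genes from the calls of the main test, without a new fit or adjustment. As the main test called 0 genes, it could only give 0 and tests nothing. Alternatives planned for TPM-like units were not needed. Transcript length, GC content and neighbouring genes came from GENCODE M21 on GRCm38, matched by symbol for 96.7% of tested genes. As this is another build, no coordinates are given.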

Results

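Hippocampal poly(A) RNA was sequenced from ovariectomised female C57BL/6J mice aged 17 weeks, in 2 groups of 3 libraries. Ovariectomy removes the ovaries, the main source of circulating estrogen. The OVX group ate a control diet, and the OVX+RJ group ate a diet with 1% royal jelly, a secretion of worker honeybees, from 8 weeks of age. The labels describe each library as a biological replicate. A sham-operated group named in the protocol text is not analysed here. The deposited table gave totals of 34718596.5, 58163785 and 40747748 counts in OVX 1, 2 and 3, and of 38487425, 39368206 and 36084588.5 counts in OVX+RJ 1, 2 and 3. Mitochondrially encoded genes took between 6.46% and 6.91% of the counts in each library. OVX+RJ 1 stood apart from the others: its mean Pearson correlation with the other 5 libraries, across genes on the log2 CPM scale, was 0.983, against 0.986 to 0.987 for the rest. The first principal component, 28.7% of the variance, separated it from the other 5.

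The comparison of OVX+RJ with OVX asks what a royal jelly diet changes in hippocampal gene expression after ovariectomy. The lowest p values belonged to activity-regulated transcription factor genes with higher values in OVX+RJ and to Zbtb16, a zinc finger transcription factor gene, with lower values. Junb was 60.0 ± 8.10 CPM in OVX+RJ and 35.9 ± 0.977 CPM in OVX (SD, n = 3 each), a log2 fold change of 0.74 (SE 0.097). Egr2 was 5.49 ± 1.63 against 1.54 ± 0.254 CPM, a log2 fold change of 1.84 (SE 0.26). Zbtb16 was 60.8 ± 1.43 against 85.2 ± 4.16 CPM, a log2 fold change of -0.49 (SE 0.066). None of the 18629 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so 0 genes were called higher and 0 lower, and the adjusted p of Junb, Egr2 and Zbtb16 was 0.121 for each. At an unadjusted p under 0.05 there were 754 genes, 398 higher and 356 lower, where chance alone gives 931. DESeq2 on the same counts called 10 genes higher and 2 lower, edgeR with robust empirical Bayes called 2 higher and 1 lower, and limma-voom called 0. Without OVX+RJ 1, edgeR called 0 genes higher and 1 lower, Phc3, which is named after its value was seen.

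The values of the 2 groups did not overlap at 1877 genes, 913 higher and 964 lower in OVX+RJ, which is 10.1% of those tested against the 10% that chance gives for 3 against 3. Among them, with predicted genes and pseudogenes left out, the 15 with the lowest p on the higher side were Junb, Egr2, Fos, Nr4a1, Egr1, Sgk1, Nufip2, Bmt2, Cry1, Arc, Npat, Cep85l, Arid5a, Pcdha6 and Tiparp, with log2 fold changes from 0.34 (Bmt2) to 1.84 (Egr2). Sgk1, a kinase gene induced by serum and glucocorticoids, was 108 ± 13.0 CPM in OVX+RJ and 75.6 ± 9.23 CPM in OVX, and Tiparp, a target of the aryl hydrocarbon receptor, was 25.1 ± 3.76 against 18.3 ± 1.47 CPM. The 15 on the lower side were Zbtb16, Xlr3a, Rps27a, Ly6c1, Xdh, Tmem204, Lime1, Mrtfa, Mertk, Lage3, Ksr1, Cables1, Adgre5, Rpl7a and Slc2a1, with log2 fold changes from -1.92 (Xlr3a) to -0.25 (Ksr1). Xdh, which encodes xanthine dehydrogenase, was 3.76 ± 0.403 against 6.98 ± 1.70 CPM, and Mertk, a receptor kinase used in phagocytosis, was 33.7 ± 1.47 against 41.7 ± 2.16 CPM. None of these 30 genes passed the adjusted threshold in the edgeR test. Xlr3a and Pcdha6 belong to families of near-identical copies or shared exons, and Rps27a and Rpl7a have processed pseudogenes, so their counts are uncertain.

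**Figure D1:**
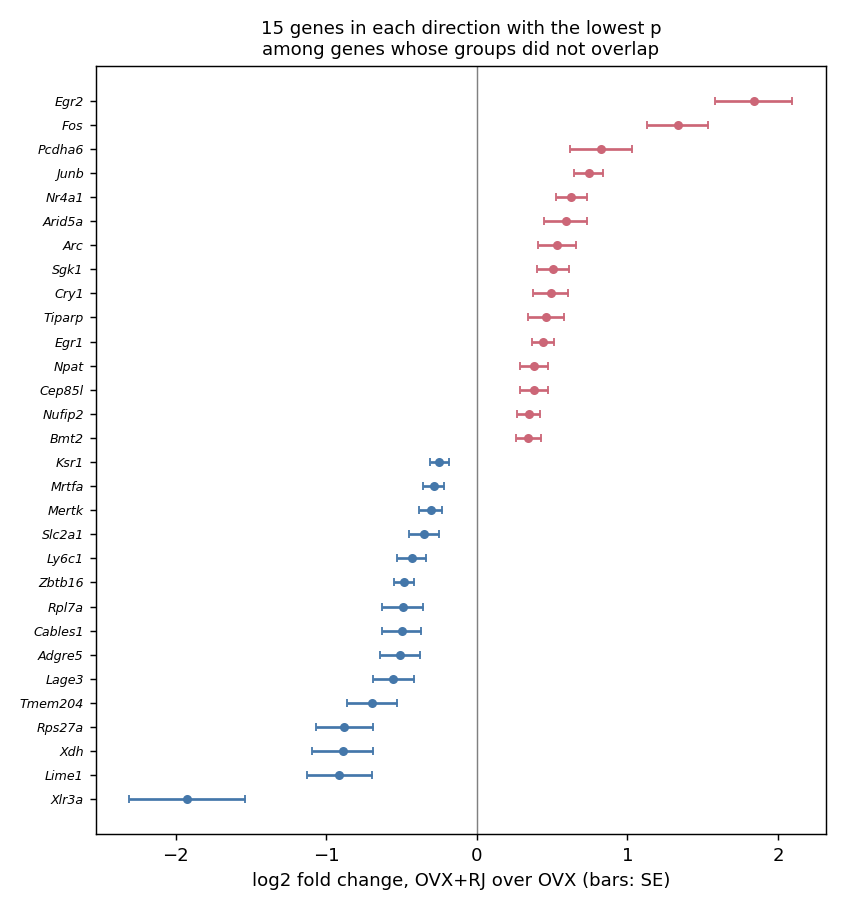
The log2 fold change of OVX+RJ over OVX (horizontal axis, points) with its standard error (bars) for the 15 genes in each direction with the lowest p among genes whose groups did not overlap, n = 3 per group. The values ran from -1.92 for Xlr3a to 1.84 for Egr2, and no gene passed an adjusted p of 0.05 in the edgeR test. Predicted genes and pseudogenes were left out of the choice.

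Immediate early genes, which neurons transcribe within minutes of activity, were higher in OVX+RJ as a list. Of 22 tested members 20 had a positive log2 fold change, with a median of 0.43. Fos was 16.1 ± 5.69 CPM in OVX+RJ against 6.39 ± 0.489 CPM in OVX, Nr4a1 was 69.8 ± 9.36 against 45.2 ± 3.83 CPM, Egr1 was 128 ± 10.2 against 94.8 ± 5.06 CPM, and Arc, whose product acts at synapses, was 119 ± 12.7 against 82.2 ± 16.0 CPM (SD, n = 3 each). The exceptions were Klf4, with a log2 fold change of -0.44, and Jun, at -0.033. The list passed camera with a preset correlation of 0.01 at an adjusted p of 4.72e-09 over the 42 lists. It did not pass with the correlation estimated from these libraries: adjusted p = 0.705 with an estimated correlation. Adjusted over the list alone, 9 members were called higher and 0 lower by edgeR (Junb, Egr2, Fos, Nr4a1, Egr1, Arc, Sik1, Nr4a3 and Gadd45b), against 0 over all genes tested. The mean log2 CPM of the list, relative to its mean over the 6 libraries, was -0.18, -0.28 and -0.16 in OVX 1, 2 and 3 and 0.46, -0.010 and 0.17 in OVX+RJ 1, 2 and 3. With OVX+RJ 1 left out the median log2 fold change was 0.23, the adjusted camera p was 8.59e-06 at the preset correlation and 0.760 with an estimated correlation, and over the list alone 8 members were called higher and 1, Klf4, lower. Sik1 and Gadd45b, at 0.79 and 0.53 with all 6 libraries, were then at 0.42 and 0.27 and not called, while the other calls over the list alone held without OVX+RJ 1. Nr4a3 was not called without OVX 1, OVX 2, OVX+RJ 2 and OVX+RJ 3 in turn, nor Sik1 without OVX 2, nor Gadd45b when any OVX library was left out.

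**Figure D2:**
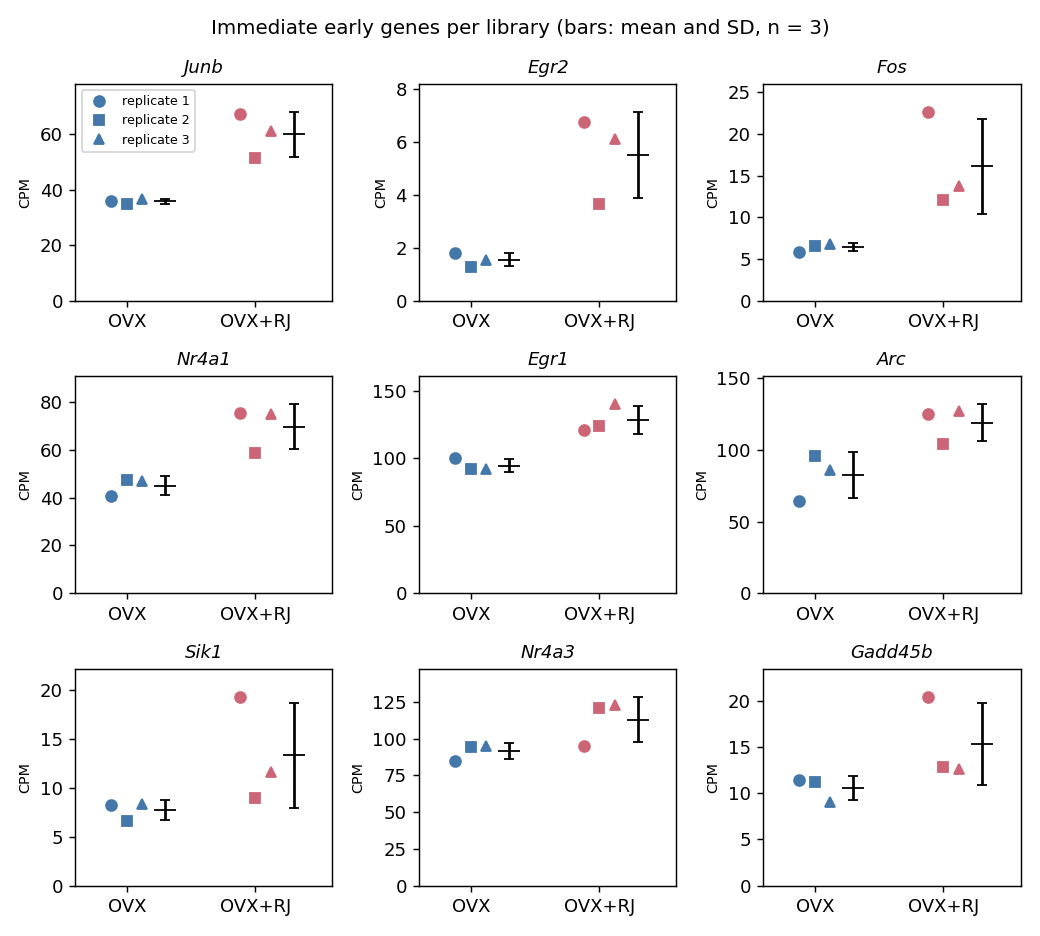
CPM (vertical axes, from 0) of the 9 immediate early genes called over the list alone, with each library as a point and the group mean and SD as black bars, n = 3. At 8 of the 9 genes each OVX+RJ library lay above each OVX library. The exception was Nr4a3, at 95.1 CPM in OVX+RJ 1 and 95.3 CPM in OVX 3. The 9 genes were chosen by p in these same libraries. Of all 22 tested members, the groups did not overlap at 9 higher and 1 lower in OVX+RJ, where chance gives 10% of genes.

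Circadian clock genes were also higher as a list: 14 of 17 tested members had a positive log2 fold change, with a median of 0.072 and an adjusted camera p of 0.0181. The call did not hold with the correlation estimated from the data, at an adjusted p = 0.762 with an estimated correlation. Cry1, a repressor of the clock, was 16.6 ± 1.89 CPM in OVX+RJ against 11.8 ± 0.50 CPM in OVX, Per1 was 87.9 ± 28.7 against 57.1 ± 4.93 CPM, Bhlhe40 was 112 ± 3.89 against 95.4 ± 2.73 CPM, and Cry2 was 133 ± 20.1 against 111 ± 3.58 CPM. Cry1, Bhlhe40 and Per1 were called higher adjusted over the list alone, 3 of 17, and 0 over all genes. The scores of the list were -0.023, -0.11 and -0.083 in OVX and 0.23, -0.027 and 0.014 in OVX+RJ. The camera call ended without OVX+RJ 1, OVX 2 and OVX 3 in turn, at medians of 0.034, 0.085 and 0.13 and adjusted p values of 0.101, 0.10 and 0.0662, and without OVX 1 the median was 0.12. The call also ended with every gene with a count tested. Per1 and Cry2, at log2 fold changes of 0.62 and 0.26, were at 0.33 and 0.13 without OVX+RJ 1. Over the list alone, none of Cry1, Bhlhe40 and Per1 was called when any OVX library was left out, nor Bhlhe40 without OVX+RJ 3, and without OVX+RJ 2 Cry2 and Ciart were also called higher and Per3 lower. Over the left-out libraries the log2 fold changes ran from 0.13 to 0.33 for Cry2, from -0.036 to 1.17 for Ciart and from -0.37 to -0.13 for Per3.

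Glucocorticoid-responsive genes went both ways. Of 19 tested members 10 had a positive and 9 a negative log2 fold change, with a median of 0.058 and an adjusted camera p of 0.634. Adjusted over the list alone, 3 were called higher by edgeR, Sgk1, Per1 and Cdkn1a, and 2 lower, Zbtb16 and Map3k6, with 0 over all genes. Map3k6 was 2.22 ± 0.313 CPM in OVX+RJ and 3.48 ± 0.256 CPM in OVX, a log2 fold change of -0.65. Fkbp5, a cochaperone induced by glucocorticoids, had a log2 fold change of -0.093, at 64.8 ± 4.47 against 69.2 ± 1.36 CPM. In fry's test of change in either direction, taken up after the data were seen, the list passed at an adjusted p of 0.0145, and in its test of one direction it was at 0.980. The former was 0.0903, 0.162, 0.0977 and 0.156 without OVX 1, OVX 2, OVX 3 and OVX+RJ 3 in turn, and 0.330 with the dentate marker mean as a covariate. Over the list alone, Sgk1 and Zbtb16 were called whichever library was left out, Per1 was not called when any OVX library was left out, nor Cdkn1a then or without OVX+RJ 1, and Map3k6 was called only with all 6 libraries and without OVX+RJ 3. Without OVX+RJ 1 the log2 fold changes of Per1 and Cdkn1a were 0.33 and 0.39, against 0.62 and 0.60, and Plin4 was called lower, at -1.42 against -0.71 with all 6 libraries and -0.44 without OVX+RJ 2.

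Ribosomal protein genes and nuclear-encoded genes of oxidative phosphorylation were lower in OVX+RJ as lists, by small amounts. Of the 84 ribosomal protein genes 72 had a negative log2 fold change, with a median of -0.093 and an adjusted camera p of 1.70e-06, and adjusted p = 0.988 with an estimated correlation. Of the 84 oxidative phosphorylation genes 63 were negative, with a median of -0.066 and an adjusted camera p of 0.000213, and adjusted p = 0.988 with an estimated correlation. Adjusted over the list alone, 0 members of either list were called by edgeR, and at an unadjusted p under 0.05 there were 10 and 7, each lower. Rps24 was 153 ± 5.76 CPM in OVX+RJ against 174 ± 2.97 CPM in OVX, and Rps28 was 17.6 ± 2.63 against 23.5 ± 4.08 CPM. Ndufa11, a subunit of complex I, was 35.8 ± 0.229 against 42.8 ± 2.54 CPM, Ndufb1 was 10.999 ± 0.976 against 15.1 ± 2.79 CPM, Ndufs5 was 52.4 ± 3.58 against 59.0 ± 0.245 CPM, and Atp5k of the ATP synthase was 11.2 ± 0.994 against 15.2 ± 3.37 CPM. The 37 mitochondrially encoded genes had a median of -0.013 and an adjusted camera p of 0.974. Unlike the other 2 lists, this one was not limited to protein-coding genes, and it holds transfer RNA genes such as mt-Tq and mt-Tm. Without OVX 3 neither list passed camera, at a median of -0.058 and an adjusted p of 0.0574 for ribosomal proteins and of -0.044 and 0.0902 for oxidative phosphorylation, and without OVX+RJ 3 the ribosomal list was at -0.056 and 0.0545. Without OVX 1 the median of oxidative phosphorylation genes was -0.10, and without OVX 3 and OVX+RJ 2 in turn Rps27a was called lower over the ribosomal list alone, with log2 fold changes from -1.08 to -0.63 over the left-out libraries.

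Pericyte and smooth muscle markers were lower in OVX+RJ: 11 of 14 tested members had a negative log2 fold change, with a median of -0.13 and an adjusted camera p of 0.0181, and adjusted p = 0.705 with an estimated correlation. Vtn was 35.4 ± 0.833 CPM against 41.3 ± 2.76 CPM, Myh11 of smooth muscle myosin was 4.59 ± 0.213 against 6.20 ± 0.868 CPM, Acta2 was 4.95 ± 0.906 against 6.32 ± 0.611 CPM, and Rgs5 was 93.3 ± 3.28 against 102 ± 6.94 CPM. No member was called adjusted over the list alone by edgeR, with 2 at an unadjusted p under 0.05. The list scores did not overlap between groups, at 0.062, 0.11 and 0.068 in OVX and -0.040, -0.12 and -0.077 in OVX+RJ. Chance alone parts 3 against 3 values 10% of the time. The scores of endothelial markers and of monoamine receptors, lists that did not pass camera, did not overlap either. The camera call ended without OVX 3, OVX+RJ 2 and OVX+RJ 3 in turn, at medians of -0.085, -0.19 and -0.14 and adjusted p values of 0.0574, 0.143 and 0.152, and without OVX 1 the median was -0.21. The call also ended with the replicate number as a block and with every gene with a count tested. Endothelial markers did not pass, at an adjusted camera p of 0.0592, with 12 of 18 negative and a median of -0.15. Without OVX+RJ 1 and OVX+RJ 2 in turn they passed at the preset correlation, at 0.00658 and 0.0304, and with only genes of a mean of at least 50 counts at 0.0364. None of these calls held with an estimated correlation, at adjusted p = 0.760, 0.980 and 0.889 in turn. Adjusted over the list alone, 2 of them were called lower: Ly6c1, at 17.5 ± 1.06 against 23.6 ± 1.63 CPM, and Slc2a1, the glucose transporter of the blood-brain barrier, at 59.1 ± 7.71 against 75.3 ± 6.34 CPM. Both calls held without OVX+RJ 1, that of Ly6c1 also held without OVX 1, where that of Slc2a1 ended, and both ended without any of the other 4 libraries. The left-out libraries gave log2 fold changes between -0.49 and -0.39 for Ly6c1 and between -0.46 and -0.27 for Slc2a1. The log2 fold changes of Ly6a and Itm2a were -0.32 and -0.15.

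Markers of dentate granule cells were lower in OVX+RJ, with 17 of 18 members negative, a median of -0.15 and an adjusted camera p of 0.0405, and adjusted p = 0.988 with an estimated correlation. The libraries of each group differed widely, with scores of 0.13, -0.16 and 0.28 in OVX and -0.10, 0.21 and -0.36 in OVX+RJ. Dsp was 58.6 ± 18.1 CPM against 74.5 ± 13.7 CPM, Lct was 36.7 ± 14.97 against 53.4 ± 6.62 CPM, Il16 was 38.2 ± 4.07 against 44.8 ± 4.12 CPM and Pdzd2 was 44.2 ± 5.35 against 53.6 ± 8.18 CPM, and 0 members were called over the list alone. The call ended without OVX 1, OVX 3, OVX+RJ 1 and OVX+RJ 3 in turn, at medians of -0.095, -0.058, -0.12 and -0.017 and adjusted p values of 0.129, 0.629, 0.0650 and 0.901. The call also ended with the replicate number as a block and with every gene with a count tested. Without OVX 2 and OVX+RJ 2 in turn the median was -0.25 and -0.31, and without OVX+RJ 2 Dsp, Lct and Il16 were among the members called lower over the list alone. Over the left-out libraries their log2 fold changes ran from -0.60 to -0.15 for Dsp, lowest in size without OVX+RJ 3, from -0.90 to -0.29 for Lct, lowest in size without OVX+RJ 1, and from -0.32 to -0.18 for Il16. Genes of adult neurogenesis did not pass, with 9 of 17 positive, a median of 0.041 and an adjusted p of 0.522. Mki67, a proliferation marker, was 3.46 ± 0.0884 against 2.57 ± 0.374 CPM, and the log2 fold changes of Sox11, Hopx and Calb2 were 0.30, -0.14 and 0.27, with Calb2 at 0.53 and called over the list alone without OVX 1, and at 0.11 without OVX 2. Dcx, expressed by new neurons, was 19.0 ± 8.71 against 19.7 ± 4.40 CPM.

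Choroid plexus markers varied between libraries within each group. Their scores were -0.45, 0.17 and -0.10 in OVX and -0.42, 0.36 and 0.44 in OVX+RJ, with a median log2 fold change of 0.030 and an adjusted camera p of 0.379. Ttr, the abundant transthyretin gene of the choroid plexus, stood at 1.85, 8.49 and 6.43 CPM in OVX and at 5.08, 14.3 and 23.1 CPM in OVX+RJ. The log2 fold changes of Clic6, F5 and Otx2 were 1.61, 0.72 and 1.29, with 0 members called over the list alone. Otx2 was at 0.78 without OVX 1 and at 2.61 without OVX 2. The list passed camera once OVX+RJ 1 was left out, with a median of 0.20 and an adjusted p of 0.00104 at the preset correlation, and adjusted p = 0.760 with an estimated correlation. Clic6 and Ttr were then called higher over the list alone, and over the left-out libraries their log2 fold changes ran from 1.21 to 1.99 and from 0.78 to 1.76. Myelin genes moved in a similar range, with scores of -0.45, 0.33 and 0.023 in OVX and -0.24, 0.058 and 0.28 in OVX+RJ, a median log2 fold change of 0.046 and an adjusted p of 0.486. At the preset correlation they passed without OVX 2, at a median of 0.26 and an adjusted p of 0.000218, and without OVX+RJ 1, at 0.17 and 0.0215. With an estimated correlation neither call held, at adjusted p = 0.874 and 0.878.

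**Figure D3:**
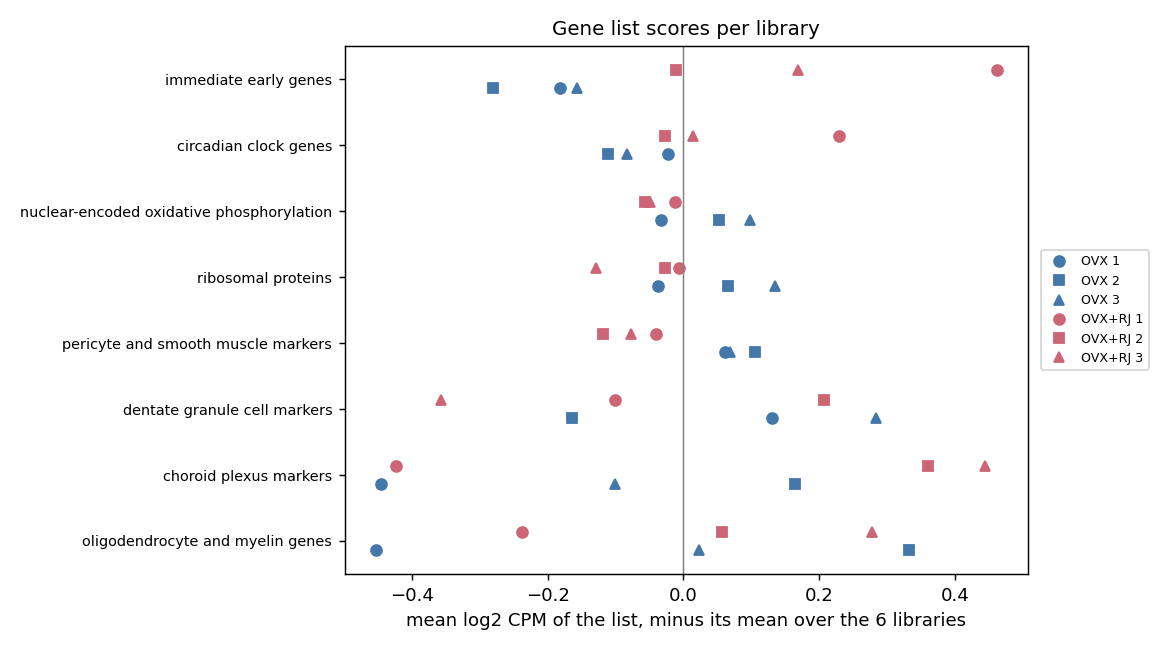
Mean log2 CPM of each gene list minus its mean over the 6 libraries (horizontal axis), with each library as a point, for the 6 lists that passed camera with a preset correlation and for choroid plexus and myelin genes. Immediate early genes and pericyte markers parted the groups, while dentate granule cell markers ran from -0.36 to 0.28 with the groups mixed. Endothelial markers and monoamine receptors, not shown, also parted the groups, and chance alone parts 3 against 3 values 10% of the time.

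Estrogen receptors and estrogen-responsive genes did not pass as a list, with 10 of 16 positive, a median of 0.014 and an adjusted camera p of 0.607. Esr1 was 3.56 ± 0.839 CPM in OVX+RJ and 3.79 ± 1.32 CPM in OVX, and Gper1 was 1.82 ± 0.315 against 2.23 ± 0.547 CPM. Esrrg, Oxtr, Esrra and Nrip1 had log2 fold changes of 0.19, 0.20, -0.11 and 0.096. Esr2 had 1, 8 and 7 counts in OVX and 6, 13 and 0 in OVX+RJ, too few to test. Neurotrophins and their receptors had a median of -0.051 and an adjusted p of 0.824. The list score was -0.53 in OVX+RJ 1 and between 0.059 and 0.14 in the other 5 libraries. Bdnf was 50.4 ± 7.80 against 52.2 ± 1.23 CPM and Igf1 was 9.64 ± 1.02 against 9.16 ± 0.363 CPM, while Vegfa, Ntrk3, Ntf3 and Igf2 had log2 fold changes of 0.19, 0.15, -0.32 and -0.12. Interferon-stimulated genes had a median of 0.080 and an adjusted p of 0.205. Ifit3 was 7.33 ± 0.506 against 5.13 ± 0.220 CPM, and Xaf1, Usp18 and Irf9 had log2 fold changes of 0.53, 1.10 and 0.28. This list passed camera without OVX+RJ 1, with a median of 0.23 and an adjusted p of 0.00272, and without OVX 2 at an adjusted p of 0.0433, both at the preset correlation. With an estimated correlation neither call held, at adjusted p = 0.760 and 0.874. The astrocyte gene Gfap was 329 ± 2.99 against 328 ± 36.4 CPM, the microglial gene Aif1 was 4.10 ± 0.548 against 3.75 ± 0.906 CPM, and App, the amyloid precursor gene, was 1711 ± 63.1 against 1665 ± 126 CPM. Chat had 0 counts in each OVX library and 4, 4 and 0 in OVX+RJ. A count of 0 allows up to 3 counts, between 0.0515 and 0.0856 CPM in these libraries.

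Across the 42 lists, 6 passed camera with a preset correlation, 2 higher and 4 lower, and 0 passed with an estimated correlation or in fry's test of one direction. In fry's test of change in either direction 4 passed: glucocorticoid-responsive genes and leptomeningeal fibroblast markers at an adjusted p of 0.0145 each, mitochondrial biogenesis at 0.0167 and immediate early genes at 0.0237. It passed 0 lists without OVX 1, OVX 2 and OVX+RJ 3 in turn and 0 with the dentate marker mean as a covariate, 5 without OVX+RJ 1 and 4 without OVX+RJ 2. Without OVX 3 it passed 2, leptomeningeal and pericyte markers, and the glucocorticoid, mitochondrial biogenesis and immediate early lists were at 0.0977, 0.0734 and 0.179. Of the lists of cell types and other tissues, 2 passed, both named above. With OVX+RJ 1 left out, 10 lists passed camera at the preset correlation, 5 of them lists of cell types and other tissues, and 0 passed with an estimated correlation or in fry's test of one direction. The circadian and dentate lists were not among these 10, which added the endothelial, choroid plexus, myelin, red blood cell, interferon-stimulated and lipid synthesis lists. Among the remaining cell type lists, the adjusted camera p was 0.142 for astrocytes (median log2 fold change -0.058), 0.561 for microglia (-0.041), 0.974 for oligodendrocyte precursors (0.020), 0.2003 for GABA interneurons (0.038), 0.297 for CA1 pyramidal cells (0.055) and 0.824 for CA3 and CA2 pyramidal cells (0.040). Astrocyte markers passed without OVX 1 (median -0.080, adjusted p 0.0400) and CA1 markers without OVX 2 (0.080, 0.0433), and with an estimated correlation these stood at adjusted p = 0.724 and 0.874. For other tissues it was 0.0970 for leptomeningeal fibroblasts (-0.20), 0.122 for red blood cells (-0.14), 0.522 for striatum (-0.066), 0.908 for neocortical layers (-0.076), 0.943 for thalamus and habenula (-8.57e-05) and 0.974 for ependyma (-0.040). Leptomeningeal markers passed without OVX+RJ 2 (median -0.21, adjusted p 0.0171) and with a mean of at least 50 counts (-0.20, 0.0282), at adjusted p = 0.908 and 0.549 with an estimated correlation. Red blood cell genes passed without OVX 1 (-0.23, 0.0194) and without OVX+RJ 1 (-0.20, 0.01998), at adjusted p = 0.724 and 0.760 with an estimated correlation. Camera gave the neocortical, ependymal and thalamic lists, and those of lipid synthesis and autophagy, the opposite sign to their medians. Synaptic lists stood at 0.561 for glutamate receptors (0.030), 0.379 for presynaptic vesicle genes (0.026), 0.666 for cholinergic genes (0.083), 0.2003 for monoamine receptors (-0.074) and 0.522 for potassium channels (0.031). Immune lists stood at 0.795 for activated microglia and cytokines (-0.045) and 0.801 for complement and MHC class I (0.0092). Stress and metabolic lists stood at 0.950 for chaperones (0.0078), 0.974 for the unfolded protein response (0.018), 0.522 for antioxidant genes (-0.044), 0.974 for cholesterol and fatty acid synthesis (-0.023), 0.974 for autophagy and lysosomes (-0.0091) and 0.858 for mitochondrial biogenesis (-0.0021). Amyloid and tau processing stood at 0.858 (-0.0078) and neuropeptides at 0.974 (0.056).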

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

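The fit with bias-adjusted quasi-likelihood, the dentate marker covariate, fry's test in either direction, and the alternatives for single lists were chosen after seeing the data. DESeq2 called 10 genes higher and 2 lower in OVX+RJ (Junb, Egr2, Fos, Egr1, Nr4a1, Arc and Sgk1 among the higher, with 3 predicted genes or pseudogenes; Zbtb16 and Xlr3a the lower), robust empirical Bayes called 2 higher (Junb, Egr2) and 1 lower (Zbtb16), and limma-voom, other scalings, other filters, an adjusted p under 0.1 and the bias-adjusted fit called 0, with 754 genes at an unadjusted p under 0.05 in the main edgeR test. A log2 fold change of at least 1 with an unadjusted p under 0.05 was met by 64 genes higher and 53 lower. With the replicate number as a block, edgeR called 1 gene higher (Gm49510) and 0 lower, 4 lists passed, and 0 lists of cell types and other tissues passed. Samples with the same number did not deviate together: the correlations of their deviations were 0.046, -0.0024 and 0.0031, and the numbers were not used as pairs. When each library was left out in turn, the genes called higher ranged from 0 to 7 and those called lower from 0 to 1. The 7 came without OVX+RJ 2: Junb, Egr2, Fos and Nr4a1, with Gm10145, Gm10705 and Rps25-ps1, and Gm49032 was then called lower. Ppia was called higher without OVX 2, Rps6ka3 higher and Gm49450 lower without OVX 3, and Phc3 lower without OVX+RJ 1. These 4, the 3 predicted genes or pseudogenes, Gm49032 and Gm49510 are named after their values were seen. Lists passing camera ranged from 1 (without OVX 3) to 10 (without OVX+RJ 1), and those of cell types and other tissues from 0 to 5, with 0 lists at an estimated correlation whichever library was left out. With every gene with a count tested, 3 lists passed, 0 of them cell types or other tissues, and with a mean of at least 50 counts 4 of those lists passed. With the dentate covariate 1 of them passed. With an estimated correlation and with fry's test of one direction 0 lists passed, and the immediate early list, whose median log2 fold change is 0.43 in both, was at an adjusted p of 0.705 and 0.395. In fry's test of either direction 4 lists passed, 1 of them of cell types and other tissues, and the immediate early list was at 0.0237, but with the dentate covariate 0 passed, and over the left-out libraries between 0 and 5. Its median kept its direction in every alternative run, between 0.23 (without OVX+RJ 1) and 0.59 (without OVX+RJ 2) over the left-out libraries, and between 6 and 13 members were called higher over the list alone. Genes and lists near 0 changed sign under some settings, and at none of the settings where the sign differed did they pass the edgeR test or camera. Esr1 was at 0.020 with limma-voom and 0.029 with the dentate covariate, Gfap at -0.0038 with every gene tested and -0.026 with the covariate, and adult neurogenesis genes at -0.026 with the covariate. Over the left-out libraries the log2 fold changes ranged from -0.32 to 0.19 for Esr1, -0.064 to 0.096 for Gfap, -0.060 to 0.24 for Aif1, -0.0057 to 0.1003 for App, -0.17 to 0.058 for Bdnf, -0.29 to 0.28 for Dcx and -0.019 to 0.12 for Igf1. The medians ranged from -0.095 to 0.20 for choroid plexus, -0.039 to 0.085 for estrogen-responsive, -0.026 to 0.11 for glucocorticoid-responsive, -0.028 to 0.23 for interferon-stimulated and -0.084 to 0.058 for neurotrophin genes. The causes were not tested, beyond the fewer samples or different genes that these settings use. Depth limits Esr2 and Chat, which had too few counts to test.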

Other observations

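OVX+RJ 1 differed from the other 5 libraries at many genes, members of the immediate early and clock lists among them. The genes named here were chosen after their values were seen. Pter was at 0.771 CPM in OVX+RJ 1 and between 88.1 and 120 CPM in the others, Fgf2, a growth factor gene, was at 0.824 CPM against 9.41 to 12.0 CPM, and B3gnt2 was at 5.37 CPM against 12.0 to 26.1 CPM. In the other direction Ccn1 was at 13.9 CPM against 2.05 to 3.78 CPM, Apold1 at 11.8 CPM against 2.28 to 4.14 CPM, Hmgb2 at 16.8 CPM against 3.51 to 5.36 CPM, and the clock genes Ciart and Nr1d1 at 22.7 CPM against 5.28 to 8.09 CPM and at 98.6 CPM against 55.97 to 63.7 CPM. Of the immediate early list, Npas4 was at 20.9 CPM against 6.17 to 9.76 CPM, Dusp1 at 24.7 CPM against 10.1 to 12.9 CPM and Btg2 at 32.9 CPM against 13.4 to 17.03 CPM. Their log2 fold changes between the groups, 0.48, 0.54 and 0.46, were -0.17, 0.076 and 0.026 without OVX+RJ 1. Csrnp1, a gene outside the lists, was at 18.1 CPM against 7.38 to 8.97 CPM.

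Tests of OVX+RJ 1 alone, of the dentate share, of a single library, of blocks of the genome and of fry's calls in other splits were chosen after the results were seen, and so was the definition of genes that lie apart. Immediate early genes had a median log2 fold change of 0.43 in OVX+RJ, and OVX+RJ 1 alone is argued against as the whole cause, though it adds to the value: without it the median was 0.23, the adjusted camera p was 8.59e-06 at the preset correlation, and 8 members were called higher over the list alone. A different share of dentate gyrus, as far as these markers track it, is argued against as the whole cause only by the size of the median. With the dentate marker mean as a covariate the median was 0.42. The adjusted camera p was then 2.35e-07 at the preset correlation, and 6 members were called higher over the list alone, against 9 without the covariate. A covariate fitted on 6 libraries is loosely estimated, so a part played by the dentate share is not excluded. With an estimated correlation the list did not pass in any of these fits (adjusted p = 0.705 with all 6 libraries, 0.760 without OVX+RJ 1 and 0.952 with the covariate), nor in fry's test of one direction (0.395, 0.597 and 0.862), and its call in fry's test of either direction, at 0.0237, was kept without OVX+RJ 1 (0.0308) and lost with the covariate (0.266). The largest absolute median over the other 9 splits of the 6 libraries into 3 and 3 was 0.32, and the 10 splits are too few for a share under 0.05. Camera at the preset correlation passed between 2 and 12 lists in each of those 9 splits, so its p values carry little weight alone. Calls over the list alone were not adjusted over the 42 lists, and they were not counted in the other splits. Members of a list may also vary together, so the number of calls is not a number of independent results. Chance, which the 10 splits cannot exclude, stays open. The diet and the circumstances of tissue collection, which the labels do not give, also stay open as untested explanations. Any of these may account for the difference.

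Ribosomal protein and oxidative phosphorylation genes were lower in OVX+RJ, with a median of -0.074 over the 165 members with a known length and GC content. A difference in how short transcripts were measured is argued against: genes matched on length, GC content and expression had a median of -0.011 over 1000 draws, and the central 95% of the draws ran from -0.022 to 0.0028. For ribosomal proteins alone the draws ran from -0.026 to 0.011, against a members' median of -0.093. The margin was narrower for oxidative phosphorylation genes alone, from -0.032 to 0.0095 against -0.065. How closely the matched genes came to the members was not measured. The camera call, which with all 6 libraries was at adjusted p values of 1.70e-06 and 0.000213 at the preset correlation and at adjusted p = 0.988 for both lists with an estimated correlation, may rest on single libraries. Without OVX 3 the oxidative phosphorylation list was at a median of -0.044 and an adjusted p of 0.0902, against -0.066 with all 6, and the ribosomal list was at -0.058 and 0.0574 without OVX 3 and -0.056 and 0.0545 without OVX+RJ 3, against -0.093. The direction of both medians held whichever library was left out. The diet, the circumstances of tissue collection and chance all stay open as untested explanations.

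OVX+RJ 1 lay apart from the mean of the other 5 libraries by over 1.5-fold and over 4 SD of those 5 (0.01 added to the variance) at 249 genes with a mean of over 100 counts, 57 higher and 192 lower, while the other libraries did so at between 12 and 26 genes. The 5 libraries that each of these was compared with included OVX+RJ 1, which can widen their SD and lower the lower counts. GC content and transcript length are argued against, since of the 241 of these genes with a known length and GC content 87.1% stayed apart after each library's trend on both was removed. A genetic difference in blocks of the genome cannot be told apart from chance here: 60 pairs of the 241 with a known position lay within 1 Mb of each other, above 94 of 100 random draws, whose mean was 45.7. No biological explanation beyond this genetic one was tested, since the labels name nothing particular to this mouse.

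The number of genes past the adjusted threshold was 0 in the real split, and the highest of the other 9 splits called 4. The number of lists past the threshold with a preset correlation was 6 in the real split and 12 in the highest other, while with an estimated correlation 0 lists passed in any split. With fry's test of either direction it was 4 in the real split and 4 in the highest other. At the preset correlation, as many lists as in the real split passed in 6 of the 10 splits, the real one included. The count of 6 lists therefore does not set the diet groups apart from other groupings. The 10 splits are too few for a share under 0.05.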
